A study of Homo sapiens with 6 samples.

How the data were processed

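RNA was sequenced from 6 libraries of H1 human embryonic stem cells, 3 wild type and 3 with E2A (TCF3) knocked out by CRISPR-Cas9. Libraries were made with a TruSeq RNA kit and sequenced on an Illumina HiSeq, per the labels. The labels gave each library its group and a replicate number from 1 to 3. They did not say whether equal numbers share a day or a culture.

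The deposited table holds FPKM values, per the file headers, in one column per library and rounded to 2 decimals; its name calls them RPKM. TopHat2 2.0.3, RSEM 1.1.20 and the build GRCh38 were named per the submitters' processing notes, without the order or the role of each. The annotation and any normalization between libraries were not given in the sources used here. The table has 18706 rows, of which 314 are at 0 in all 6 libraries. RefSeq's gene table for GRCh38 matched 18375 rows on the Entrez Gene ID, 17947 of them protein coding, and supplied the coordinates. Transcript GC content and length could be had for 18112 rows (96.8%). Mitochondrially encoded genes were not among the rows, so that list was not tested.

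FPKM gives no counts. For transcripts up to 1500 bases with less than 1 FPKM, the values of a library were searched for the total at which they become whole numbers of fragments. The best total was 22000000 to 22300000 fragments, by library, with 66.3% to 69.3% of the values within 0.2 of a whole number, against 40% by chance. This estimate rests on the annotated length less 40 bases and was used to describe depth and to compare it between libraries, not in any test of genes. At that depth 1 FPKM of a 2 kb transcript stands for about 43.3 fragments, so values far below 1 FPKM rest on few fragments. Squared differences between libraries of one group had a median of 2.18 to 8.68 times that of sampling noise, so no 2 were taken for one library. The Pearson correlation of their log2 values across genes was 0.996 to 0.998.

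The groups were compared on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, for the 13305 genes with a mean of at least 0.5 FPKM over the 6 libraries, with a variance trend and no rescaling of the values. Tests were two-sided, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. TCF3 was also tested with an exact permutation test. The design had been written for RPKM, and the same test was used for FPKM.

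Gene lists were fixed before the data were examined: 33 lists for states of pluripotency, signalling, cell types these cultures could hold, cell cycle, stress and metabolism. The 32 with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation and with fry. Chromosome medians were set against 10000 random sets of as many genes matched on mean expression, computed in Python 3.11.15.

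The genes named in the text were chosen by a rule fixed beforehand. TCF3 came first. Then, of genes with an adjusted p under 0.05, no overlap between the groups and a mean of at least 2 FPKM in the higher group, the 12 largest rises and the 12 largest falls were taken. Each list added up to 4 members with an adjusted p under 0.05 and the largest change, or the 2 with the highest mean where fewer than 2 passed; a list could also be described by its counts alone. XIST and genes of the Y chromosome were left out of the tables of genes, and 2 genes that the rule named are not reported here.

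Alternatives planned beforehand were pseudocounts of 0.1 and 1, no filter, a filter at 2 FPKM, rescaling by median ratios, quantile normalization, other variance models, library weights, the replicate number as a block, and leaving out each library in turn. A correction for GC content and length was added after seeing the data. It subtracts from each library the smooth trend (natural splines with 5 degrees of freedom) of its deviations from the gene means, and 13156 genes had the values it needs. It moved the median log2 fold change of all genes from -0.04 to -0.09, and centring each library on its median afterwards moved it to 0.03, a shift of all genes alike; corrected values are given without that centring.

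The fit was tested on simulated data made from the values of these libraries, with 200 changed genes among 13305. It called 100% of the genes changed by -2 on the log2 scale, 94% of those changed by -1, 64% of those changed by -0.5 and 76% of those changed by 0.5, and 0.0458% of the unchanged genes. With a GC trend added to the libraries it called 15.9% of the unchanged genes without the correction, and 0.0617% of the unchanged genes among 13156 with it. The added trend was a preset line on GC content and length, not fitted to these libraries, and the correction is built to remove such a trend. These shares therefore do not show how many of the real calls are false.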

Results

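Gene expression was measured by RNA-seq in H1 cells, an established line of human embryonic stem cells, grown on Matrigel in the defined medium TeSR-E8. Of the 6 libraries, 3 came from unedited wild-type cells and 3 from cells in which E2A was knocked out with CRISPR-Cas9. E2A is the protein product of TCF3, a class I basic helix-loop-helix transcription factor (an E protein) that pairs with tissue-specific partners and is held back by ID proteins. The deposited values were FPKM, fragments scaled to the length of the transcript and to the total of the library, for 18706 genes. The sum of FPKM was 492775 to 507639 in the wild-type libraries and 543803 to 548096 in the knockout libraries. The total number of fragments behind each library, estimated from the spacing of the low values, was 22000000 to 22300000, which puts about 43.3 fragments behind 1 FPKM of a 2 kb transcript. The labels did not say whether the replicates were separate cultures or separate clones, so the p-values measure the spread between these libraries, part of which may be technical.

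The first question was how much of the targeted transcript the edited cells still carried. TCF3 (Entrez Gene 6929, GRCh38 chromosome 19, 1609292 to 1652615) stood at 121 ± 4.51 FPKM in the wild type and at 72.0 ± 1.61 FPKM in the knockout (SD, n = 3 each), 59.5% of the wild-type mean. The wild-type libraries read 121, 116 and 125 FPKM and the knockout libraries 72.6, 73.2 and 70.1 FPKM, so the groups did not overlap. The log2 fold change was -0.74 with a standard error of 0.05 (limma adjusted p = 3.156e-06). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The transcript fell and was not lost; a small insertion or deletion can leave a transcript in place, and where in the gene the edit lies was not given in the sources used here, so the level checks the labels only in its direction.

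**Figure D1:**
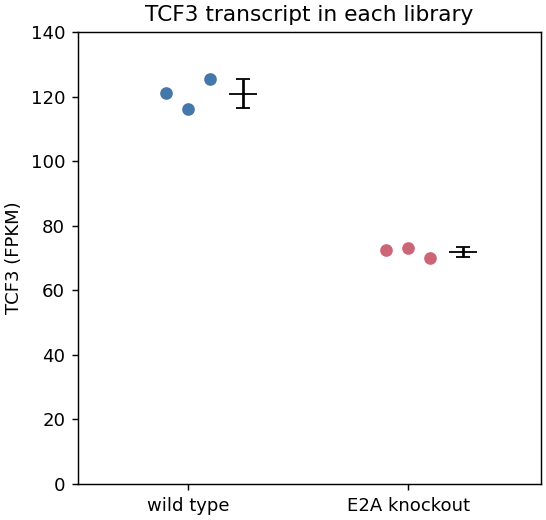
TCF3 transcript level (FPKM, vertical axis from 0) in the 3 wild-type and 3 knockout libraries, one point per library, with the group mean and SD as a bar beside the points. The wild-type libraries lie at 116 to 125 FPKM and the knockout libraries at 70.1 to 73.2 FPKM.

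The second question was which genes differed between knockout and wild type. Some of the largest falls left a transcript nearly absent from the knockout. CTSF, which encodes the lysosomal protease cathepsin F, fell from 10.5 ± 0.336 to 0.0433 ± 0.0404 FPKM, and EDNRB, the endothelin receptor type B, from 9.77 ± 1.41 to 0.03 ± 0.0361 FPKM (SD, n = 3 each). NNAT, the imprinted gene of neuronatin, fell from 5.27 ± 0.561 to 0.163 ± 0.137 FPKM, and VPS37B, a subunit of the ESCRT-I sorting complex, from 2.88 ± 0.327 to 0.04 ± 0.0173 FPKM. Others fell strongly and were still present: FKBP11, a peptidyl-prolyl isomerase of the secretory pathway, fell from 33.0 ± 0.275 to 3.06 ± 0.643 FPKM, and OTX2, a homeobox factor of primed pluripotent cells and of the anterior neural plate, from 7.50 ± 0.942 to 1.16 ± 0.135 FPKM, a log2 fold change of -2.27 with a standard error of 0.11.

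The other falls among the 12 largest were in CBR1, NPTX1, MYLPF, RGS5, PRAC1 and CXCL5, with log2 fold changes from -2.52 for CBR1 to -1.88 for CXCL5. The limma adjusted p of the 12 falls lay between 2.684e-09 for CTSF and 7.573e-06 for CXCL5. The paralogs CBR1 and CBR3, carbonyl reductases at 36070024 to 36073164 and at 36135079 to 36146562 on GRCh38 chromosome 21, moved in opposite directions. CBR1 fell from 3.14 ± 0.157 to 0.14 ± 0.121 FPKM while CBR3 rose from 1.003 ± 0.273 to 5.88 ± 0.555 FPKM (SD, n = 3 each). Fragments shared between such paralogs can be split by the counting, so the 2 values are less certain than those of single-copy genes.

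The largest rises reached lower folds than the largest falls. NDUFA4L2, a mitochondrial protein known as a hypoxia-induced gene, rose from 0.663 ± 0.30 to 5.19 ± 0.856 FPKM, and NDRG1, also known to be induced by hypoxia, from 6.09 ± 1.62 to 21.0 ± 2.86 FPKM (SD, n = 3 each). The metallothioneins MT1X and MT2A, small metal-binding proteins, rose from 102 ± 19.2 to 367 ± 18.4 FPKM and from 21.9 ± 1.43 to 61.6 ± 9.92 FPKM (log2 fold changes 1.86 and 1.46, or 1.58 and 0.97 corrected); they belong to a family of near-identical copies, which makes their separate values uncertain. LGALS1, which encodes galectin-1, rose from 74.6 ± 8.86 to 215 ± 14.9 FPKM. Further rises among the 12 largest were in ECHDC3, C2CD4B, CHST8, SCGB3A2 and TIAF1, with log2 fold changes from 1.85 for ECHDC3 to 1.40 for TIAF1; TIAF1 overlaps another gene, MYO18A, and is uncertain for that reason. The limma adjusted p of the 12 rises lay between 1.884e-07 for CHST8 and 3.187e-05 for TIAF1.

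**Figure D2:**
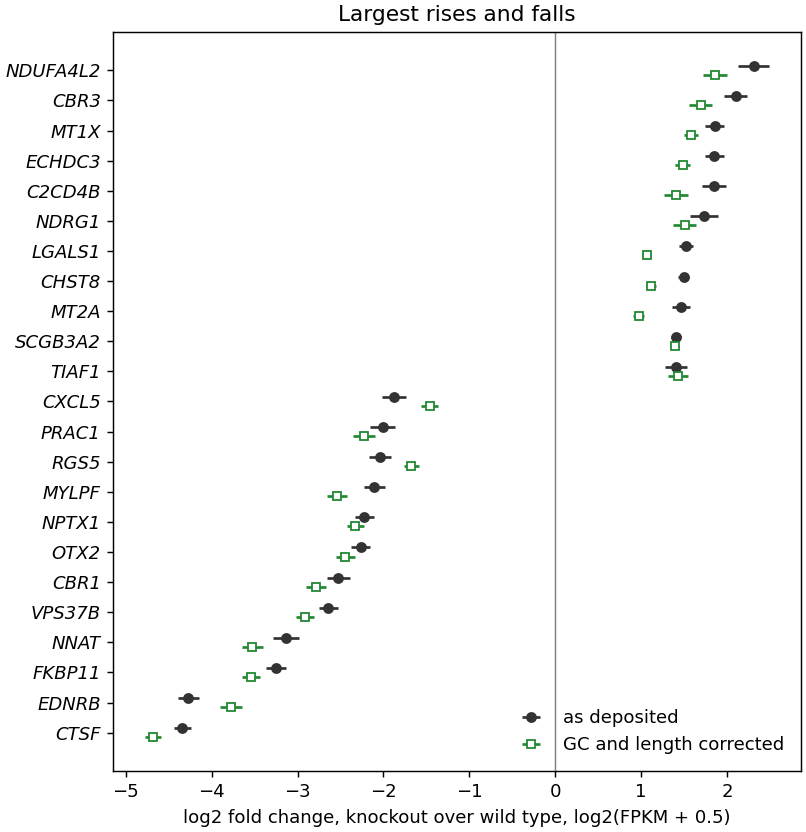
Log2 fold change, knockout over wild type, on the log2(FPKM + 0.5) scale (horizontal axis) for 11 of the 12 largest rises and the 12 largest falls; filled circles are the values as deposited and open squares the values after a correction for transcript GC content and length, with standard errors as bars. All 23 genes keep their direction, from CTSF at -4.34 to NDUFA4L2 at 2.31 as deposited.

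Across 13305 tested genes, limma called 8322 (62.5%) at an adjusted p under 0.05, of which 3564 were higher and 4758 lower in the knockout. Of these, 443 changed at least 2-fold, 66 upward and 377 downward. The 3 knockout values all lay on one side of the 3 wild-type values in 9306 genes (69.9%), against 10% by chance for a single gene. Genes that follow one trend across the libraries move to one side together, so this is no count of separate differences. The size of the change went with the make-up of the transcript. Among 5 equal classes of genes by GC content, the median log2 fold change was -0.54 in the lowest class and 0.25 in the highest, and 258 of the 377 genes that fell at least 2-fold were in the lowest class. With this trend and that on length removed, limma called 6875 of 13156 genes, 1867 higher and 5008 lower, and 121 at 2-fold or more, 24 upward and 97 downward; 638 genes were called in both fits with opposite sign. The majority direction depends on the scaling: with the corrected libraries also centred on their medians, 3794 genes were higher and 2769 lower. Leaving out wild-type replicate 1 lowered the count at 2-fold or more to 235.

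**Figure D3:**
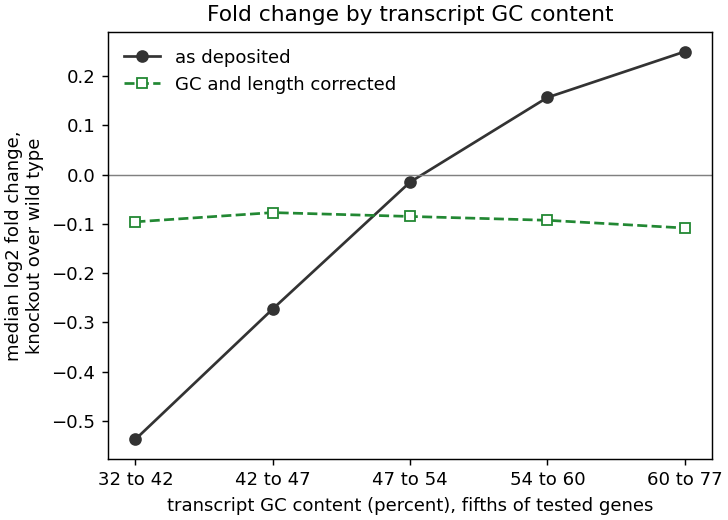
Median log2 fold change, knockout over wild type (vertical axis), in 5 equal classes of the tested genes by transcript GC content in percent (horizontal axis); filled circles are the values as deposited, open squares those after the GC and length correction. The deposited values run from -0.54 to 0.25, and the corrected ones lie between -0.08 and -0.11.

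Gene groups fixed beforehand were then compared, with pluripotency first. Their corrected counts come from the fit without centring. Over all genes that fit called 1867 higher and 5008 lower, so a lean to lower counts is not particular to a list. Of the 23 tested genes of core pluripotency, 4 rose and 13 fell (6 and 13 corrected; medians -0.17 as deposited and -0.18 corrected, on the log2 scale). L1TD1, LIN28B and POLR3G fell, with log2 fold changes of -1.06, -1.04 and -1.02 (-0.64, -0.46 and -0.49 corrected), and UTF1, a chromatin-associated factor of pluripotent cells, rose by 0.92 (0.44 corrected). The list as a whole was not past the threshold (camera adjusted p = 0.245). The 3 factors most used to define the state were looked up after their values were seen: POU5F1 rose from 1645 ± 96.9 to 2094 ± 64.3 FPKM (SD, n = 3 each; log2 fold change 0.35, limma adjusted p = 0.000405, or 0.16 corrected). SOX2 stood at 87.8 ± 3.22 and 82.6 ± 2.80 FPKM in wild type and knockout, not called as deposited (log2 fold change -0.086, adjusted p = 0.151) and called lower when corrected (-0.18, adjusted p = 0.00612). NANOG stood at 62.4 ± 4.03 and 55.6 ± 4.23 FPKM, called lower as deposited (-0.17, adjusted p = 0.0474) and not when corrected (-0.086, adjusted p = 0.157). The median log2 fold change over all genes in that uncentred corrected fit was -0.09. The corrected -0.18 of SOX2 may be in part that shift of all genes alike, so no fall of SOX2 is drawn from it.

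Of 19 listed markers of naive pluripotency, the state of the preimplantation epiblast, 10 passed the filter of 0.5 FPKM and were tested. Of these, 9 rose, and all 10 when adjusted over the list alone (median log2 fold change 0.46). ALPPL2 and ESRRB had wild-type means under 0.5 FPKM (0.333 and 0.433) and passed through their knockout values (0.77 and 0.707). Genes as low that did not rise were left out, so the share that rose depends on the filter. All 10 were expressed at a low level: NLRP7 rose from 1.22 ± 0.280 to 2.38 ± 0.142 FPKM, KLF4 from 0.603 ± 0.101 to 1.09 ± 0.270 FPKM and TFAP2C from 4.64 ± 0.279 to 6.67 ± 0.821 FPKM (SD, n = 3 each). The list was past the threshold (camera adjusted p = 0.00908, or 0.00170 corrected for GC content and length), but not with an estimated correlation (adjusted p = 0.544) or without the filter on low values (adjusted p = 0.143). With the correction 4 of the 10 members were called, and KLF4 was no longer among them (log2 fold change 0.52, or 0.33 corrected). Of 17 markers of the primed state, 4 rose and 10 fell as deposited and corrected, or 4 and 11 adjusted over the list alone as deposited. The largest falls were in OTX2, in FGF2, a growth factor used to maintain primed cells (log2 fold change -1.35, -0.71 corrected), and in PTPRZ1 (-1.06, -0.58 corrected), while CYTL1 rose by 1.01 (0.90 corrected). That list was not past the threshold (camera adjusted p = 0.21).

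Signalling groups split in direction. In the NODAL-SMAD2/3 list, 4 of 17 genes rose and 9 fell (3 and 10 corrected): CER1, a secreted NODAL antagonist, fell from 6.39 ± 0.527 to 2.06 ± 0.453 FPKM, and SKIL and ACVR2B fell with log2 fold changes of -0.99 and -0.85 (-0.59 and -0.44 corrected). Among BMP targets and the ID family, 3 of 10 rose and 2 fell (4 and 3 corrected). The inhibitory SMAD7 and SMAD6 rose, with log2 fold changes of 0.84 and 0.52 (0.45 and 0.32 corrected). ID1, an inhibitor that binds E proteins, fell from 67.0 ± 1.37 to 43.6 ± 1.14 FPKM and ID3 from 91.3 ± 3.57 to 70.6 ± 8.46 FPKM (SD, n = 3 each; log2 fold changes -0.61 and -0.37, or -1.01 and -0.74 corrected). Of 8 tested genes of the E-protein and class II family, 2 rose and 2 fell (0 and 3 corrected). The falls as deposited were the other E proteins, TCF12 at a log2 fold change of -1.04 (-0.71 corrected) and TCF4 at -0.86 (-0.89 corrected); the rises were MESP2 at 0.78 and TCF15 at 0.49, neither called when corrected (0.34 and 0.057). None of these 3 lists was past the threshold (camera adjusted p = 0.568, 0.66 and 0.55).

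Targets of FGF-ERK signalling rose in 10 of 17 genes and fell in 2 (8 and 3 corrected; camera adjusted p = 0.0444, or 0.00245 corrected); with an estimated correlation the adjusted p was 0.544. DUSP5, a phosphatase of ERK, rose from 10.9 ± 0.523 to 19.98 ± 1.21 FPKM, FOS by 0.59 and ETV4 by 0.57 on the log2 scale (0.41 and 0.20 corrected), while SPRED1 fell by 0.58, a change that the correction removed (0.045). The call was lost without wild-type replicate 2, wild-type replicate 3 or knockout replicate 3, at adjusted p = 0.0533, 0.0561 and 0.0882, and with a filter at 2 FPKM (0.0939), one prior variance for all genes (0.0634) or library weights (0.0727). Immediate early and heat shock genes rose in 9 of 14 and fell in 2 (5 and 2 corrected; camera adjusted p = 0.00908). JUN, a subunit of AP-1, rose from 7.82 ± 0.747 to 15.9 ± 0.282 FPKM, while HSPH1, a heat shock protein, fell with a log2 fold change of -1.02 (-0.57 corrected). The median of this list was 0.37 as deposited and 0.03 corrected, and its call was lost with the correction (adjusted p = 0.0686) and with an estimated correlation (adjusted p = 0.544).

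Glycolysis and hypoxia genes rose in 15 of 24 and fell in 5 (12 and 7 corrected; camera adjusted p = 0.0155, or 0.0141 corrected), with a median log2 fold change of 0.30 as deposited and 0.12 corrected; with an estimated correlation the adjusted p was 0.601, and the call was also lost with quantile normalization (0.187), a filter at 2 FPKM (0.0629) and library weights (0.0727). Beside NDRG1, CA9, the hypoxia-induced carbonic anhydrase, rose from 0.813 to 1.97 FPKM and the glycolytic ALDOC from 78.0 to 119 FPKM (log2 fold changes 0.90 and 0.62, or 0.52 and 0.33 corrected). ADM, another gene known to be induced by hypoxia, fell with a log2 fold change of -0.88 (-1.19 corrected). Of 20 genes of amino acid and unfolded protein stress, 2 rose and 12 fell. The largest falls, as log2 fold changes, were in SLC7A11, the cystine transporter, at -1.64 (-0.90 corrected), in CHAC1 at -1.08 (-1.50 corrected), in PSAT1, an enzyme of serine synthesis, at -0.93 (-0.80 corrected), and in SLC7A5, an amino acid transporter, at -0.90 (-1.09 corrected). This list missed the threshold as deposited (camera adjusted p = 0.0879) and passed it when corrected (adjusted p = 0.00445), with 15 members lower and 1 higher. It also passed without the filter on low values (0.0323), with quantile normalization (0.0118), without wild-type replicate 1 (0.0304) and without knockout replicate 1 (0.0221). In fry, which does not compare a list with all other genes, 21 of the 32 lists were called. The fry adjusted p of this list was 0.0026, so that call is not particular to it. With an estimated correlation it missed the threshold as deposited (adjusted p = 0.601) and when corrected (adjusted p = 0.645).

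**Figure D4:**
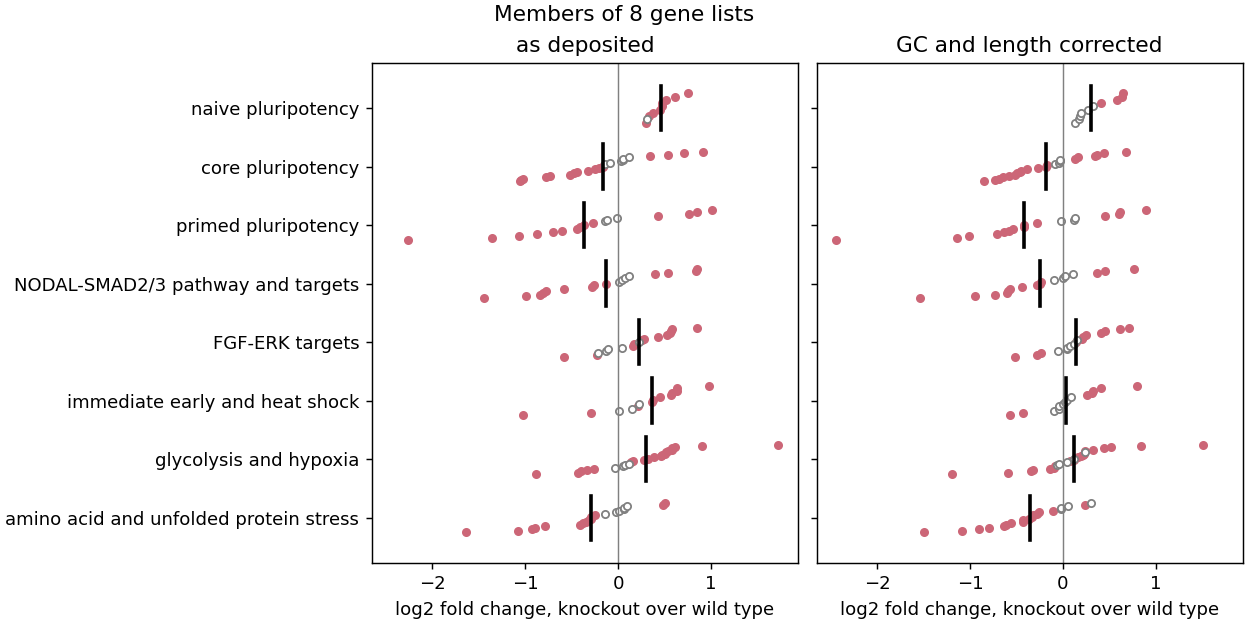
Log2 fold change, knockout over wild type (horizontal axis), of each tested member of 8 gene lists, as deposited on the left and corrected for GC content and length on the right; filled points have a limma adjusted p under 0.05, open points do not, and the black bar is the list's median. The median of the naive pluripotency list is 0.46 and 0.30, and that of immediate early and heat shock genes is 0.37 and 0.03.

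Markers of other cell types were not past the threshold as groups. Only genes past the filter were tested, as few as 5 of 22 listed mesoderm, 5 of 17 definitive endoderm and 5 of 20 amnion and trophoblast genes. More of the neural crest (8 of 14) and fibroblast lists (10 of 14) could be tested. The results rest on these genes and do not speak for those below the filter. Of 10 tested neural ectoderm genes 1 rose and 5 fell (1 and 6 corrected), among them SOX3 at a log2 fold change of -0.99 (-1.36 corrected) beside OTX2. Of 9 neuronal genes 4 rose and 3 fell (3 and 4 corrected), with GAP43 at a log2 fold change of 0.87 (0.81 corrected) and MAP2 at -0.75 (-0.31 corrected). Of 7 genes of the primitive streak 3 rose and 1 fell (1 and 1 corrected): SP5 rose from 0.163 to 1.38 FPKM and FGF8 fell from 1.57 to 0.903 FPKM (log2 fold changes 1.49 and -0.55, or 1.09 and -1.07 corrected). Definitive endoderm had 1 higher and 2 lower of 5 (1 and 4 corrected), and mesoderm 3 lower of 5 (4 corrected), with TNNT2 at -1.32 on the log2 scale (-1.69 corrected). Neural crest had 2 higher, or 3 adjusted over the list alone, and 3 lower of 8 (2 and 2 corrected); NGFR rose from 11.9 ± 1.49 to 32.0 ± 2.52 FPKM (SD, n = 3 each). Amnion and trophoblast had 2 higher and 0 lower of 5 (1 and 1 corrected), and germ cell 2 higher and 2 lower of 5 as deposited and corrected, with MAGEA4 at 1.20 and DAZL at -1.03 on the log2 scale (1.06 and -0.60 corrected). Among 10 fibroblast genes 4 rose, or 5 adjusted over the list alone, and 3 fell (3 and 4 corrected): COL3A1 and TAGLN had log2 fold changes of -1.86 and -1.43 (-1.81 and -1.83 corrected), while THY1, which pluripotent cells also carry, rose by 0.85 (0.60 corrected). The camera adjusted p of these 9 lists lay between 0.122 and 0.844.

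The remaining lists were also short of the threshold, with camera adjusted p between 0.122 and 0.987. WNT targets had 4 higher and 3 lower of 12 (3 and 5 corrected), and NOTCH targets 5 and 2 of 11 (4 and 2 corrected), with DLL3, a NOTCH ligand, rising from 15.9 ± 1.69 to 37.3 ± 0.969 FPKM (SD, n = 3 each). Epithelial junction genes had 11 higher and 7 lower of 19 (4 and 11 corrected). Their corrected median log2 fold change, -0.11, lay near the -0.09 of all genes in that uncentred fit. Mesenchymal genes had 4 higher and 8 lower of 14 (5 and 7 corrected). G2-M genes had 5 higher and 12 lower of 20 (1 and 10 corrected), led by CENPF, a kinetochore protein, at a log2 fold change of -1.57 (-0.97 corrected). G1-S genes had 2 higher and 8 lower of 21 (2 and 15 corrected), CDK inhibitors 3 and 1 of 5 (0 and 2 corrected), p53 targets 7 and 8 of 20 (2 and 10 corrected), and apoptosis genes 4 and 4 of 14 (2 and 6 corrected). Cholesterol synthesis had 7 higher and 7 lower of 20 (3 and 6 corrected), and the interferon response 7 and 2 of 13 (4 and 2 corrected). Genes of the 20q11.21 gain that recurs in cultured stem cells had 6 higher and 5 lower of 18 (5 and 6 corrected; median log2 fold change 0.10, or 0.00 corrected), and imprinted genes 4 higher and 8 lower of 14 (1 and 7 corrected), with NNAT and IGF2 the largest falls. In 28 of the 32 lists the counts adjusted over the list alone were those over all genes. The median, the mean and the camera test did not share one sign for BMP targets, definitive endoderm, neural crest, fibroblast, apoptosis and cholesterol synthesis, none of them past the threshold.

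The last question was whether whole chromosomes moved. The median log2 fold change of a chromosome's genes ran from -0.35 on chromosome 13 to 0.19 on chromosome 19, and 18 of 23 chromosomes were past the threshold against 10000 random sets matched on mean expression (two-sided permutation test, Benjamini-Hochberg adjusted; 0.0002 was the smallest unadjusted p the sets could give). With the correction for GC content and length none of these 18 was past it, and 2 others were: chromosome 21, with a median of -0.18, and chromosome 1, with a median of -0.06 (adjusted p = 0.0069 each, against 0.1131 and 0.3021 as deposited); the median over all genes was -0.09. Groupings that mixed wild-type and knockout libraries gave up to 18 chromosomes past the threshold, and up to 7 gene lists in camera.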

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

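The GC and length correction, its centred form and the tests named with them were chosen after seeing the data; the other settings were planned. TCF3 was called in each setting, at a log2 fold change of -0.68 to -0.94. The count of changed genes stayed between 6563 and 10865, and without one library each between 6960 and 8200. The count at 2-fold or more depended on the pseudocount: 827 at 0.1 (142 higher, 685 lower) and 246 at 1 (36 higher, 210 lower), as low genes shrink less or more by construction. It was 134 higher and 182 lower after quantile normalization, and 90 higher and 238 lower with library weights. Without one library it ran from 235 (without wild-type replicate 1) to 616, with 51 to 88 higher and 184 to 528 lower (248 lower without knockout replicate 1). The corrected fit gave 1867 higher genes (27.2% of calls, against 42.8%) and 121 at 2-fold or more (24 and 97); centred on the median it gave 3794 higher and 2769 lower (57.8% higher), and 107 at 2-fold or more (40 and 67). Quantile normalization left 52.3% of calls higher.

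Of the 4 fixed lists past the threshold, 1 was left with a filter at 2 FPKM, where the naive list had too few genes, 2 with library weights and 0 with an estimated correlation; fry, which asks another question, called 21. Quantile normalization added core pluripotency, G2-M and amino acid stress (0.0118 each), and no filter added neural ectoderm (0.0219) and amino acid stress (0.0323). Without one library 3 to 5 lists were called. Chromosome shifts fell from 18 to 2 in both corrected fits, and without one library numbered 15 to 17. Why the other changes arose was not tested. Deviations from the group means correlated at -0.39, 0.05 and -0.35 between libraries of equal replicate number. The GC trend also moves these deviations, so they cannot tell whether equal numbers share a day or a culture. With the replicate block 6973 genes were called, 443 at 2-fold or more, and 4 lists.

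Directions turned in these cases, all far from the threshold for lists (adjusted p) except where stated. p53 targets turned with the filter at 2 FPKM (0.726), median ratio rescaling (0.974), library weights (0.644), the replicate block (0.88), ranks (0.975) and without single libraries (0.753 to 0.967). Definitive endoderm turned without a filter (0.47) and without wild-type replicate 3 (0.907; 0.68 to 0.937 over all single libraries), apoptosis with quantile normalization (0.948), and cholesterol synthesis with it (0.596) and in fry (0.651). In the corrected fit the E-protein list turned (0.601, centred 0.44), as did epithelial junction (0.498, centred 0.782) and, centred, fibroblast (0.782), which also turned in fry at 0.00613. Log2 fold changes that turned were TBX6 -0.021, SPRED1 0.045, CCNE2 0.027, XIAP 0.014 and PMAIP1 0.013 when corrected, and SPRED1 0.17, CCNE2 0.15, XIAP 0.14, PMAIP1 0.14, HMGCS1 0.047, CYP51A1 0.0076 and DDX58 0.095 when also centred, where SPRED1 and PMAIP1 were called. Of 138 named genes, all called as deposited, 23 lost their call when corrected, 18 when also centred, and at most 3 of those tested in any other setting. With 3 libraries a group and values rounded to 2 decimals, changes in genes below about 1 FPKM are the least certain.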

Other observations

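Tests in this part were all chosen after the results they bear on had been seen, apart from limma's calls, camera's calls on the fixed lists and the chromosome shifts, all as deposited. Targets of SRF and YAP, transcriptional regulators that answer to actin tension, were put together as a list after TAGLN and CTGF had been seen to fall. Of 20 tested, 14 fell and 1 rose, and with the GC and length correction 17 fell. The corrected median log2 fold change of the list was -0.54, against -0.09 over all genes. TPM1 fell from 264 to 104 FPKM, MYL9 from 239 to 155 FPKM, CTGF from 109 to 61.6 FPKM, CYR61 from 40.4 to 26.7 FPKM and AMOTL2 from 19.1 to 11.3 FPKM, while the muscle actin ACTG2 stood at 28.6 and 29.7 FPKM. The metallothioneins, also listed after 2 of them stood among the largest rises, rose in 7 of 7 tested genes and in 6 of 7 when corrected, with a median log2 fold change of 1.20 (0.72 corrected). As these lists were picked from these libraries, their camera adjusted p (0.000165 and 3.09e-05, or 0.0819 and 0.12 with an estimated correlation) is no independent evidence. Of 22 cancer-testis genes 2 were expressed highly enough to test, MAGEA4 and CTCFL, and both rose; CTCFL had a log2 fold change of 1.27.

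The broad shift, 8322 of 13305 genes, went with transcript composition. GC content and length took up 48.1% of the variance of the fold changes across genes, so a technical bias may account for a large part of the shift. Of 441 genes called at 2-fold or more and tested in both fits, 85 were at 2-fold or more with the same sign after the correction, but all except 2 were still called with the same sign, so the correction shrank these changes and did not end most of them. The correction left 6875 calls, of which 4049 were called as deposited with the same sign, 638 with the opposite sign and 2188 not at all. Bias that it misses, or removes only in part, would also leave calls, so these do not show whether bias was the whole cause. The estimated totals do not separate the groups, as the highest was 1.01 times the lowest. They are the totals behind the FPKM values, so a difference in depth before any normalization would not show. The GC slopes of the 2 groups did not overlap, with a gap of 0.16 on the log2 scale per 10 GC points. They were -0.24, -0.13 and -0.07 in the wild-type libraries and 0.21, 0.15 and 0.09 in the knockout libraries. The trend thus also varied between libraries of one genotype, and that part is not an effect of the knockout. For the gap between the groups, library preparation or sequencing that differed cannot be told apart from an effect of the knockout, since each group may have been handled as one batch. The real grouping gave 8322 and 443 calls and the highest of the other splits 0 and 0. In each case 1 of 10 splits was as large, too few splits for a share under 0.05. The other splits all mixed wild-type and knockout libraries, so the difference between these entered the spread within each group. That spread holds calls down, so the 0 and 0 do not measure how many calls arise by chance.

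A few transcripts fell to a small share of their wild-type level. By a rule of a call, no overlap, at least 2 FPKM in the wild type and a knockout mean under 10% of it, 8 genes on 6 chromosomes qualified (CTSF, EDNRB, FKBP11, NNAT, VPS37B, CBR1, NPTX1 and PRAC1). GC content and length do not explain them, as their median log2 fold change went from -2.89 to -3.22 with the correction. Loss of the surrounding region is not supported either: the median over these genes of their neighbours' median change within 500 kb was -0.063, and no neighbourhood's median was below -0.17, though EDNRB had 1 tested neighbour. By the mirrored rule 0 genes were gained. This leaves open a clonal difference between the edited cells and the wild type, other than the edit. Such a difference may, like loss of E2A, silence single genes. If the knockout libraries came from a single clone, which the labels did not say, they could not separate the 2. Libraries known to come from independently edited clones would be the test.

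The rise of 4 fixed lists was uneven in its support. A call left after the correction does not show that GC content and length were not the whole cause. For naive pluripotency, FGF-ERK targets and glycolysis and hypoxia the call stayed, with a camera adjusted p after the correction of 0.0017, 0.00245 and 0.0141. That holds at the preset correlation; with an estimated one the corrected adjusted p was 0.645, 0.645 and 0.764, and none of the 4 lists passed as deposited either. The glycolysis and hypoxia median fell from 0.30 to 0.12 (SD over members 0.52 and 0.50), so GC content and length may account for much of that rise. For immediate early and heat shock genes they may be the whole cause of the rise as a list: the adjusted p rose to 0.0686 as the median fell from 0.37 to 0.03 and the mean from 0.28 to 0.076, more than the SD over members did (0.49 to 0.34). Over all genes the median moved from -0.04 to -0.09 in that uncentred fit, so the list medians fell in part with that shift. The corrected median of the immediate early list still lay above that of all genes, and camera's direction stayed up. Single members are another matter, as 5 of the 9 called higher stayed so when corrected, JUN among them at 0.80. Of the 10 splits of the libraries, 2 gave at least as many lists as the 4 of the real grouping, and the highest other gave 7, and for chromosomes 2 of the 10 splits reached 18 and the highest other also gave 18. These are too few splits for a share under 0.05, and the mixed groupings still hold part of the difference between knockout and wild type. No shift of state is drawn from the naive list.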
